A study of Mus musculus with 12 samples.

How the data were processed

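Total RNA from mouse lung was hybridised to 12 Affymetrix arrays in 4 groups of 3. Groups came from the sample titles and the treatment protocols, which gave the same assignment for every array. A description field that called every sample a control animal was not used. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled cRNA was hybridised.

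The deposited table holds log2 values, 1 per probe set and array, that the authors had normalised between arrays before submission. Per the submitters' processing notes MAS5 and GCRMA were used, with neither role nor version given. The method of normalisation, the background correction and the scaling of the table are not given in the sources used here. The table was checked: values ran from 2.99 to 15.02, array medians from 7.0 to 7.07, and 0 array columns were identical. It holds no detection calls, so a low level could not be told from background. The number of arrays limits the precision.

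Of 45101 probe sets 64 control probe sets were left out. Probe sets were kept when their mean over the 12 arrays was above the 40th percentile, a log2 level of 6.42, which left 27022. Of 45037 non-control probe sets 34945 carried 1 gene symbol, 932 carried several and 9160 none, and only the first kind was used for genes. Symbols were compared with the reference gene table through the Entrez identifier, which changed 0 of them. Each gene was represented by its probe set with the highest mean, giving 12921 genes, of which 5853 had more than 1 probe set past the filter. No genome build is named with the table, and no coordinates are given.

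A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 2.99 prior degrees of freedom). The comparisons were rhPBEF, ventilation and both against control, both against ventilation, both against rhPBEF, and the interaction. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. An exact test of 3 against 3 arrays cannot give a two-sided p below 0.1, so the moderated test was used. Levels are given as mean and SD and differences with their standard error.

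Gene lists were written from general knowledge before the data were examined, as were the groups, the comparisons, the filter, the threshold, the named-gene rule and all alternatives except those said to be added. The 37 lists held 665 entries for 653 genes, of which 547 were tested, and 35 lists had the 5 tested members required. Lists were tested with camera in limma at a preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the 35 lists. Members past 0.05 are counted over all genes and again adjusted over the list alone.

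The genes named were, for comparisons with control, the 10 largest rises and 10 largest falls among genes past 0.05 whose groups did not overlap. The other pairwise comparisons took 5 and 5, and the interaction took the 5 smallest p-values when no gene passed. Nampt and the 4 tested members with the largest change in each described list were added. Names of uncharacterised transcripts were left out.

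Alternatives changed the filter, the normalisation, the variance model, the handling of several probe sets per gene, the replicate block, the arrays in the fit and the unit counted, and left out each array in turn. A fit without 2 arrays high in skeletal muscle genes and a ventilation effect averaged over rhPBEF were added after seeing the data.

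The steps were tested on simulated data, drawn around the real gene means with the real residual spread and 200 changed genes in each of 5 rounds. For rhPBEF against control the fit recovered 52.8% of genes changed by 0.5 on the log2 scale and 87.6% of those changed by 1, with 4.16% false among the calls. For ventilation against control it recovered 47.0% and 82.4%, with 5.40% false. A list shifted by 0.5 passed in 5 of 5 rounds in both, and with an estimated correlation in 3 of 5 for rhPBEF and 5 of 5 for ventilation. Unshifted lists passed 0 of 170 times in each. Simulated genes varied independently, unlike real ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.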

Results

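Lung RNA from mice aged 8 to 12 weeks was measured on 12 Affymetrix arrays, each holding 45101 probe sets. The arrays formed 4 groups of 3. Control mice received phosphate-buffered saline. A second group was ventilated for 4 hours at a tidal volume of 30 ml per kg, a large breath size used to injure the lung mechanically. Another group received recombinant human PBEF (rhPBEF) into the trachea, 20 µg per mouse in 1.5 µl of water per gram of body weight. The remaining group received both rhPBEF and ventilation. PBEF, pre-B-cell colony-enhancing factor, is the secreted form of nicotinamide phosphoribosyltransferase, an enzyme of NAD synthesis that the mouse gene Nampt encodes. The labels do not give the time between instillation and tissue collection, and they do not say whether the ventilated mice received saline. Nothing in the labels states that replicates were different mice, so p-values measure the spread between these arrays.

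Expression ran from 2.99 to 15.02 on the log2 scale, and the medians of the 12 arrays lay between 7.0 and 7.07. Arrays of a group correlated at 0.983 to 0.997 over the 45037 non-control probe sets, before the filter. The first principal component held 43.3% of the variance. It placed all 3 control arrays at -0.39, the ventilated arrays from -0.12 to 0.00, the rhPBEF arrays from 0.02 to 0.27, and the arrays of the combined treatment from 0.00 to 0.54. Ventilation replicate 2 stood alone on the second component (21.8% of the variance), at 0.88 against -0.25 to 0.16 for the other 11 arrays.

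The first comparison asked what rhPBEF alone did to the lung. Chemokines, most of them attracting neutrophils, made up 6 of the 10 largest rises. Cxcl2, a neutrophil chemokine, rose 173-fold, from a log2 level of 5.37 ± 0.09 (SD, n = 3) in control to 12.80 ± 0.10 (SD, n = 3), with a limma adjusted p of 7.97e-05. Cxcl3 rose 109-fold, Cxcl5 31.5-fold and Cxcl1 19.2-fold, although the 3 probe sets of Cxcl1 ran from 1.29 to 6.58 on the log2 scale. Il6, the acute inflammatory cytokine, rose 26.2-fold to 9.32 ± 0.99 (SD, n = 3) with an adjusted p of 0.0078. The acute phase gene Saa3 rose 36.0-fold, the anion exchanger gene Slc26a4 25.6-fold, and Ccl20, a chemokine for dendritic cells and lymphocytes, 14.7-fold. Control levels of Cxcl2, Cxcl3, Cxcl5 and Il6 lay below 6.42, the level used as the filter on mean expression. So did those of several genes named further on, among them Ccl3, Slfn4, Saa1, Clec4e and Csf3. No measure of background comes with the values, so the folds of all these genes are sizes as measured.

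Altogether 158 of 12921 genes passed an adjusted p of 0.05 for rhPBEF against control, 121 higher and 37 lower, and 100 of them changed at least 2-fold. With each array centred on its median, 157 genes passed, 138 higher and 19 lower. Among the 10 largest rises were also Ccl3, a chemokine for monocytes, at 15.3-fold and Slfn4, an interferon-inducible gene of myeloid cells, at 14.1-fold. Falls were smaller than rises. Btc, which encodes the epidermal growth factor receptor ligand betacellulin, fell by 0.98 ± 0.13 (SE) on the log2 scale, and the death receptor gene Tnfrsf21 fell by 0.83 ± 0.11. The other falls among the 10 largest were -1.33 for the potassium channel gene Kcnk2, -1.03 for the alanine aminotransferase gene Gpt2, -0.84 for Amz1, -0.77 for F3, which encodes tissue factor, and -0.74 for Mycl. The epithelial keratin gene Krt19 had -0.72, the homeobox gene Irx5 -0.69 and Haus8 -0.66.

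**Figure D1:**
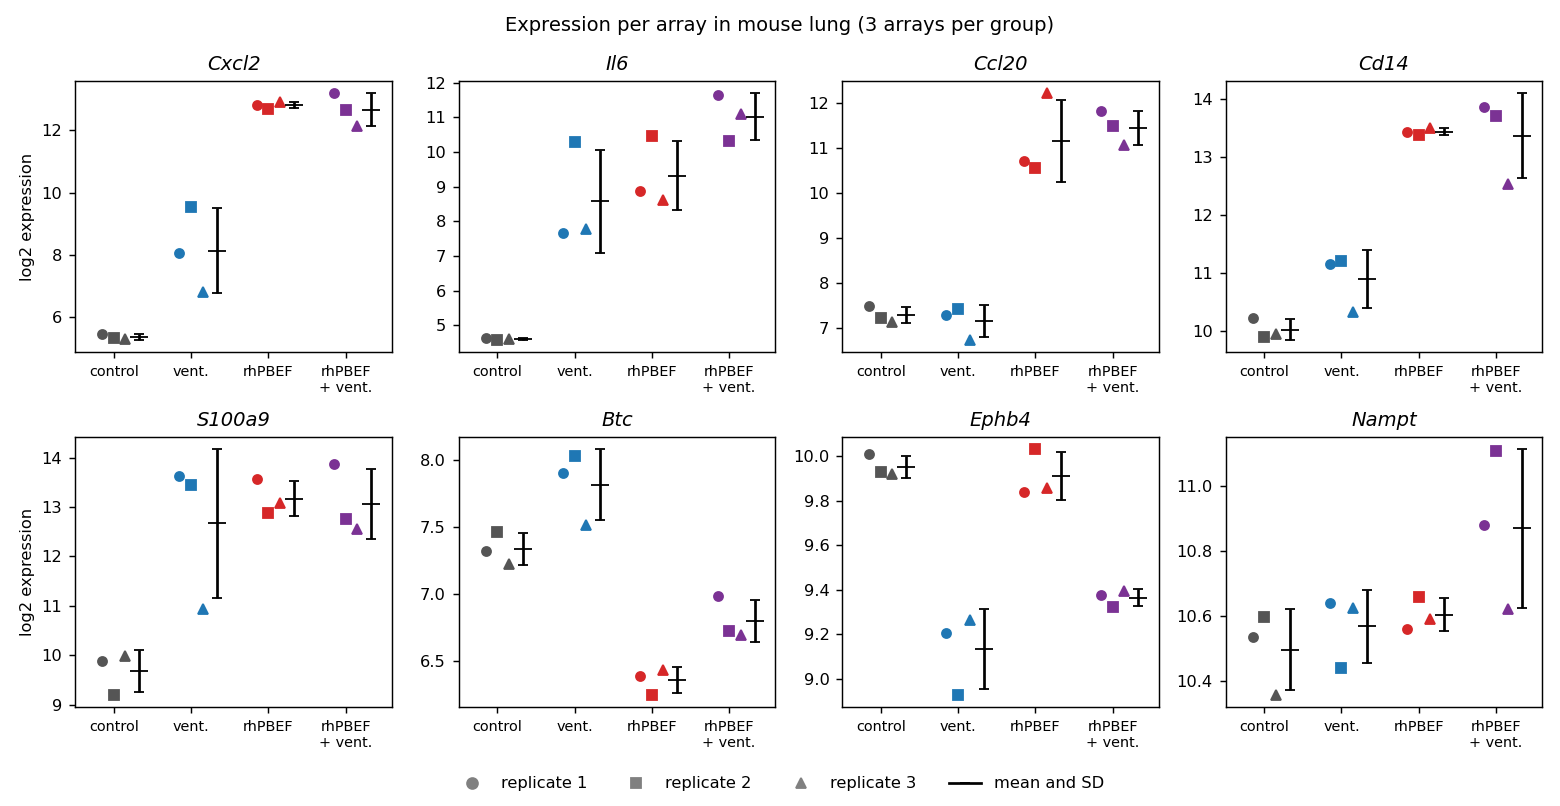
Log2 expression (y axis) of 8 genes on each of the 12 arrays, by group (x axis, 3 arrays per group). Symbols are replicates 1 to 3 and the bar is the mean with its SD, for example 5.37 for Cxcl2 in control and 12.80 after rhPBEF.

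Of 35 gene lists tested, 16 stood apart after rhPBEF with camera's preset correlation of 0.01, and 0 with an estimated correlation (lowest adjusted p = 0.122). Of 26 chemokine genes tested, 9 rose after rhPBEF and 17 did not pass, and 16 rose when adjusted over the list alone. The list as a whole stood above other genes (camera adjusted p = 1.18e-20 with a preset correlation of 0.01), but not with an estimated correlation (adjusted p = 0.122 with an estimated correlation). Of 18 NF-kB targets and regulators, 9 rose, among them Cd83 by 2.86, Tnfaip2 by 2.79 and Tnfaip3, an inhibitor of the pathway, by 2.38 on the log2 scale, and Selp, encoding P-selectin, stood at 2.10 ± 0.85 (SE, adjusted p = 0.227). Adjusted over the list alone, 15 rose and 1 fell. Its list adjusted p was 2.44e-19 with the preset correlation, against adjusted p = 0.122 with an estimated correlation. Among 17 Toll-like receptor and acute phase genes 8 rose, or 11 adjusted over the list alone, including the endotoxin co-receptor gene Cd14 at 10.6-fold and the cytokine signalling inhibitor Socs3 at 6.28-fold. Saa1 stood at 9.67-fold with an adjusted p of 0.132. That list had an adjusted p of 1.30e-17 with the preset correlation, against adjusted p = 0.122 with an estimated correlation. Of 15 inflammatory cytokines 5 rose, or 10 adjusted over the list alone (list adjusted p = 5.35e-14, adjusted p = 0.122 with an estimated correlation). The granulocyte growth factor gene Csf3 rose 8.11-fold, while Il1b stood at 9.43-fold (adjusted p = 0.0618) and Csf2 at 7.15-fold (adjusted p = 0.0567).

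Of 17 neutrophil markers 4 rose after rhPBEF, namely Clec4e, S100a9, S100a8 and Il1r2, by 3.65, 3.48, 3.05 and 2.92 on the log2 scale. The other probe set of Clec4e stood at 2.0. Adjusted over the list alone 13 rose and 1 fell (list adjusted p = 1.58e-14, adjusted p = 0.226 with an estimated correlation). The metallothionein genes Mt2 and Mt1 rose 3.01-fold and 2.53-fold, and the mitochondrial superoxide dismutase gene Sod2 rose 2.52-fold. They were 3 of the 4 rising members among 19 oxidative stress genes, of which 6 rose and 1 fell adjusted over the list alone, and the heme oxygenase gene Hmox1 stood at -1.27 ± 0.54 (SE, adjusted p = 0.244). The list adjusted p was 0.000156 with the preset correlation, against adjusted p = 0.232 with an estimated correlation. None of 18 interferon-stimulated genes passed over all genes, and 8 did when adjusted over the list alone. Rsad2 stood at 2.68-fold (adjusted p = 0.108), Gbp2 at 2.44-fold, Ifit1 at 1.98-fold and Irf1 at 1.74-fold. Their list adjusted p was 4.69e-08 with the preset correlation, against adjusted p = 0.336 with an estimated correlation.

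Heat shock genes were lower as a list after rhPBEF. None of 14 passed over all genes or adjusted over the list alone, 13 had a negative fold change and the median was -0.92 (list adjusted p = 0.0105, adjusted p = 0.783 with an estimated correlation), and the list p was 0.0817 without rhPBEF replicate 3. Hspa1b stood at -2.59 ± 1.05 (SE), Hspa1a at -2.49 ± 1.20, Hsph1 at -2.28 and Dnajb1 at -1.77. The skeletal muscle list was higher (list adjusted p = 0.0436, adjusted p = 0.783 with an estimated correlation). Its mean lay 2.82 log2 units above control in rhPBEF replicate 2 against -0.14 and -0.55 in replicates 1 and 3, and the list p was 0.658 without replicate 2. Acta1, Tnni2, Tnnt3 and Mylpf stood at 1.53, 1.41, 1.22 and 1.10, with none of 9 members past in either adjustment. NAD metabolism genes, the pathway of PBEF itself, did not stand apart (0 of 14 past, 1 higher and 2 lower adjusted over the list alone, list adjusted p = 0.725). Parp14 stood at 0.76, Aox3 at -0.55, Nadk at 0.46 and Nadsyn1 at -0.39. Leaving out a control array or rhPBEF replicate 1 or 2 lowered the count of genes for rhPBEF against control to 55, 44, 48, 56 or 51 in that order, and without rhPBEF plus ventilation replicate 2 it was 105. It rose to 265 without ventilation replicate 2 and to 358 without rhPBEF plus ventilation replicate 3. Arrays outside the comparison enter through the shared estimate of spread.

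The second comparison asked what ventilation without rhPBEF did. No group was ventilated at another tidal volume. In every comparison of ventilation, effects of the large breath size therefore cannot be told apart from those of being ventilated at all or of the procedure around it. A single gene passed, Ephb4, an endothelial receptor of the ephrin family, which fell by 0.82 ± 0.10 (SE) on the log2 scale, from 9.95 ± 0.05 to 9.13 ± 0.18 (SD, n = 3 each, limma adjusted p = 0.0431). An unadjusted p under 0.05 was reached by 2004 genes, 719 higher and 1285 lower. Inflammatory genes had large differences that did not pass, with a wide spread between the 3 ventilated arrays. Il6 stood 15.7-fold above control at 8.58 ± 1.49 (SD, n = 3) with an adjusted p of 0.0909, and Il1b stood at 5.21-fold with 0.194. Tnfsf9 stood at 2.61-fold and the interleukin 1 antagonist gene Il1rn at 2.37-fold. None of the 15 inflammatory cytokines passed, and 3 did when adjusted over the list alone (list adjusted p = 4.34e-05, adjusted p = 0.470 with an estimated correlation).

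Of 35 lists 18 stood apart after ventilation, 12 higher and 6 lower, and 0 with an estimated correlation. Immediate early genes, which are induced soon after a stimulus and many of which encode transcription factors, gave the smallest list p for ventilation. None of 26 passed over all genes, 10 rose adjusted over the list alone, and 25 had a positive fold change with a median of 0.81 (list adjusted p = 2.93e-13, adjusted p = 0.468 with an estimated correlation). Egr2 stood at 3.29-fold, Nr4a1 at 2.97-fold, Fos at 2.56-fold and Fosb at 2.44-fold. The list mean was 1.60 log2 units above control in ventilation replicate 2 and 0.40 and 0.39 in replicates 1 and 3. Neutrophil markers followed, with 0 of 17 past, 11 higher adjusted over the list alone and a median of 1.56 (list adjusted p = 5.49e-12, adjusted p = 0.468 with an estimated correlation). Mmp8, the neutrophil collagenase gene, stood at 8.19-fold, Clec4d at 8.07-fold, S100a9 at 7.91-fold (adjusted p = 0.110) and Clec4e at 6.44-fold. Their mean was 2.28 and 2.14 in replicates 1 and 2 but 0.49 in replicate 3. Of 17 mechanical stretch and matrix injury genes none passed and 3 did adjusted over the list alone (list adjusted p = 3.95e-05, adjusted p = 0.468 with an estimated correlation). The hyaluronan synthase gene Has1 stood at 2.80-fold, the thrombospondin gene Thbs1 at 2.41-fold, Adamts4 at 2.0-fold and Hbegf at 1.95-fold.

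Endothelial, adipocyte and smooth muscle markers were lower as lists after ventilation, as were ciliated cell, fibroblast and cardiac muscle markers. Of 22 endothelial markers none passed over all genes and 6 fell adjusted over the list alone, with 20 negative (list adjusted p = 6.71e-05, adjusted p = 0.468 with an estimated correlation). Eng, a co-receptor of the transforming growth factor family, stood at -0.66 ± 0.09 (SE, adjusted p = 0.0625), Ramp2 at -0.72, the transcription factor gene Sox18 at -1.28 and Tmem100 at -1.39. All 8 adipocyte markers were negative and 7 fell adjusted over the list alone (list adjusted p = 4.78e-05, adjusted p = 0.468 with an estimated correlation). Pck1, encoding the gluconeogenic enzyme PEPCK, stood at -1.99 ± 0.33 (SE, adjusted p = 0.0848), the adipokine gene Adipoq at -1.42, Cidec at -1.17 and Plin4 at -0.99. The adipocyte list mean of control replicate 1 was 0.68 above the group mean and that of control replicates 2 and 3 -0.42 and -0.26. All 13 smooth muscle markers were negative, with none past in either adjustment (list adjusted p = 0.000211, adjusted p = 0.473 with an estimated correlation). Cnn1 stood at -0.76, Actg2 at -0.73, Myh11 at -0.72 and Myl9 at -0.65. That list's p was 0.140 without ventilation replicate 1, where its mean was -1.03 against -0.18 and -0.30 in replicates 2 and 3. All 14 cardiac muscle markers were negative (list adjusted p = 0.0194, adjusted p = 0.755 with an estimated correlation). The cardiac list mean was -1.71, -0.18 and 0.10 in ventilation replicates 1 to 3. In control replicates 1 to 3 it was 0.58, -0.43 and -0.16, with replicate 1 highest as for adipocyte markers. What set these arrays apart was not tested.

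Heat shock genes did not stand apart with ventilation when all arrays were used (list adjusted p = 0.128, 0 of 14 past), but the result turned on single arrays. With the preset correlation the list was higher without ventilation replicate 3 (median 0.64, adjusted p = 0.000136), without ventilation replicate 1 (median 0.22, adjusted p = 0.0475) and without both arrays high in skeletal muscle genes (adjusted p = 0.000145), and lower without ventilation replicate 2 (median -0.60, adjusted p = 0.00117). Their list mean was 1.67 in replicate 2 but -0.12 and -1.06 in replicates 1 and 3. Bag3 stood at 1.0, Chordc1 and Stip1 at 0.59 and Dnajb1 at -0.33. The first 3 were negative without replicate 2, and Dnajb1 was positive without control replicate 3 or without ventilation replicate 3. Skeletal muscle genes did not stand apart with all arrays (list adjusted p = 0.323, 0 of 9 past) and were higher without ventilation replicate 1 (adjusted p = 0.0451), with Acta1 at 1.78, Tnni2 at 1.09, Mylpf at 0.77 and Tnnt3 at 0.72. Their list mean was 1.98 in replicate 3 against -0.54 and -0.12 in replicates 1 and 2. The number of genes past was 43 without ventilation replicate 3, 15 without replicate 1, 5 without replicate 2, 6 without rhPBEF replicate 2 and 11 without rhPBEF plus ventilation replicate 3. It was 0 without any other single array, and 34 without both arrays high in skeletal muscle genes, a setting chosen after seeing the data.

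The combined treatment was then set against control. The neutrophil chemokines, cytokines and acute phase genes led again, and endothelial genes were among the falls. Cxcl2 rose 156-fold to 12.66 ± 0.53 (SD, n = 3, limma adjusted p = 0.00014), Cxcl3 96.0-fold, Il6 85.2-fold to 11.02 ± 0.67, Saa3 39.2-fold and Cxcl5 39.1-fold. Slc26a4 rose 24.8-fold, Cxcl1 20.1-fold, Ccl20 18.1-fold, Clec4e 17.2-fold and Saa1 17.0-fold. On the other side Smad6, an inhibitor of bone morphogenetic protein signalling, fell by 1.58 ± 0.24 (SE), Sox18 fell by 1.44 ± 0.29, and Dbp, an output gene of the circadian clock, fell by 1.36 ± 0.36 on the log2 scale. The other falls among the 10 largest were -2.09 for the cholecystokinin receptor gene Cckar, -1.66 for Ankrd63, -1.55 for Tppp, -1.38 for the eosinophil-associated ribonuclease gene Ear3, -1.36 for the cytochrome gene Cyp1a1, -1.24 for Nrn1 and -1.20 for Myb. In all, 1136 genes passed, 508 higher and 628 lower, 256 of them at least 2-fold, of which 224 were higher. With each array centred on its median, 932 passed, 525 higher and 407 lower, so which direction held more genes depends on the scaling.

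By list, 14 of 18 NF-kB targets and regulators rose (15 rose and 1 fell adjusted over the list alone, list adjusted p = 7.51e-17, adjusted p = 0.164 with an estimated correlation), with Cd83 at 8.37-fold, Tnfaip2 at 7.20-fold and Tnfaip3 at 6.43-fold, and Selp standing at 7.38-fold (adjusted p = 0.0578). Chemokines rose for 13 of 26 members, or 17 adjusted over the list alone (list adjusted p = 7.00e-15, adjusted p = 0.164 with an estimated correlation). Toll-like receptor and acute phase genes rose for 11 of 17, or 14 adjusted over the list alone (list adjusted p = 7.91e-15, adjusted p = 0.164 with an estimated correlation), including Ptx3, a soluble pattern recognition gene, at 10.6-fold and Cd14 at 10.1-fold. Neutrophil markers rose for 10 of 17, or 13 adjusted over the list alone (list adjusted p = 1.07e-11, adjusted p = 0.256 with an estimated correlation), among them Il1r2 at 11.6-fold, Clec4d at 10.6-fold and S100a9 at 10.4-fold. Inflammatory cytokines rose for 10 of 15, with 11 higher and 1 lower adjusted over the list alone (list adjusted p = 7.77e-11, adjusted p = 0.219 with an estimated correlation), including Csf3 at 9.87-fold, Il1b at 9.76-fold and Il1rn at 6.25-fold. Of 24 called gene and comparison pairs with several probe sets, 6 had probe sets over 1 log2 unit apart: Cxcl1 (1.37 to 6.72 here) and Clec4e (2.35 to 4.10 here) in this comparison and after rhPBEF alone, and Il1rn (0.66 to 2.64) and Fosl2 in this comparison.

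Immediate early genes rose for 6 of 26 members, or 9 adjusted over the list alone (list adjusted p = 5.19e-10, adjusted p = 0.387 with an estimated correlation). Junb rose 3.42-fold, Egr2 2.94-fold and Fosl2 2.68-fold (log2 1.42, against 0.16 for its other probe set), while Egr1 stood at 2.62-fold (adjusted p = 0.132). Of 13 coagulation and fibrinolysis genes 2 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00478, adjusted p = 0.256 with an estimated correlation). The fibrinogen gene Fgg rose 3.94-fold, while Tfpi2 stood at 4.42-fold (adjusted p = 0.051), F10 at 2.16-fold and Plaur at 2.06-fold. Of 22 endothelial markers 5 fell, also when adjusted over the list alone, among them Sox18, Sox17 at -0.86, Ramp2 at -0.77 and Egfl7 at -0.76 (list adjusted p = 0.0317, adjusted p = 0.598 with an estimated correlation). Among 14 NAD metabolism genes 1 rose and 2 fell (4 and 4 adjusted over the list alone, list adjusted p = 0.838). The mitochondrial deacetylase gene Sirt3 fell by 0.50, and Parp14 stood at 0.92 (adjusted p = 0.0522), Aox3 at -0.91 and Nnmt at 0.49. The count of 1136 genes became 152 without rhPBEF plus ventilation replicate 1, 171 without replicate 2 and 2498 without replicate 3. It was 189, 192 and 263 without control replicate 1, 2 or 3, and 1815 without ventilation replicate 2.

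**Figure D2:**
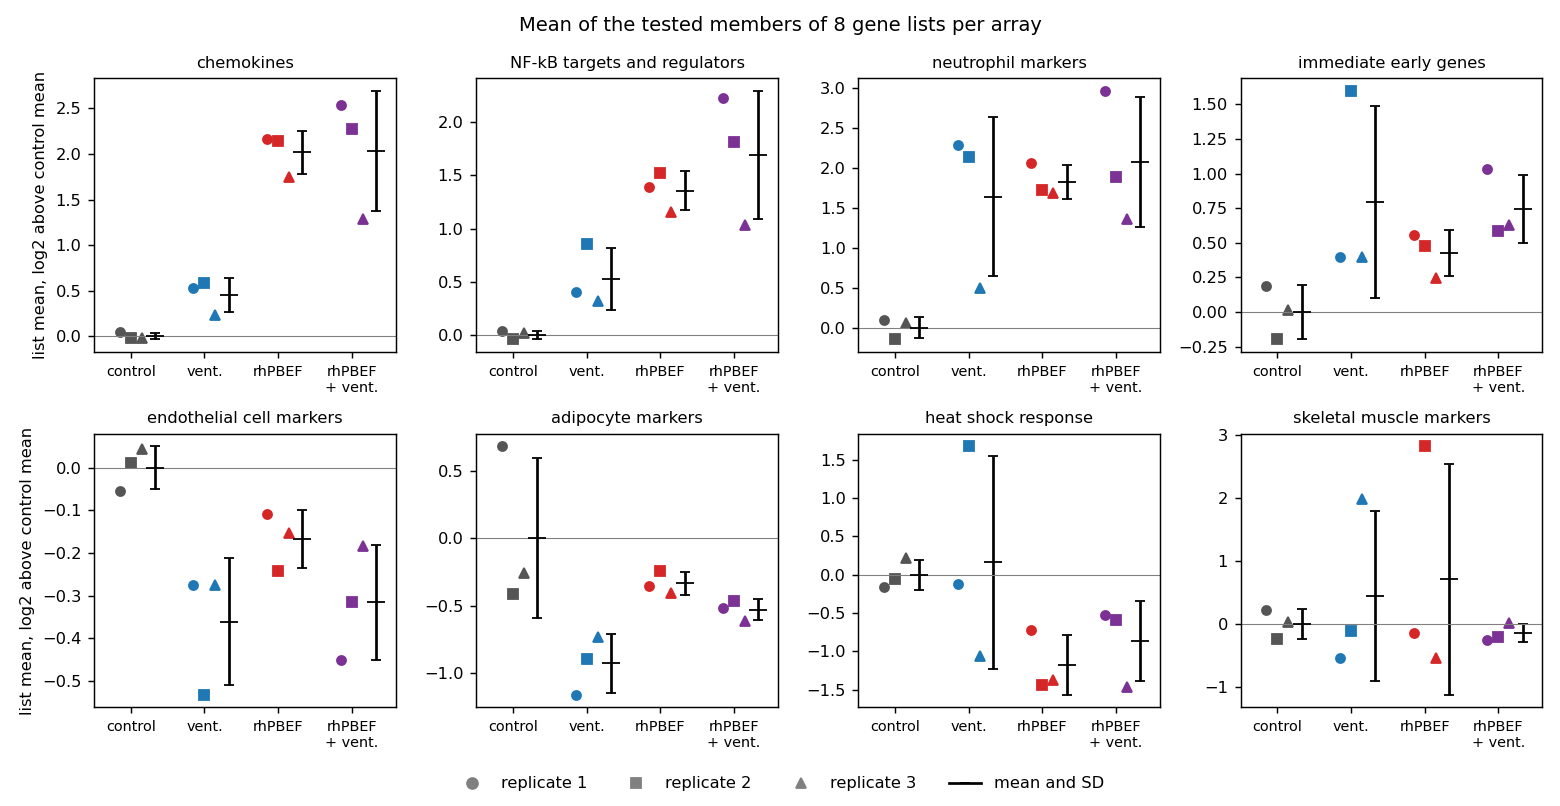
Mean over the tested members of 8 gene lists on each array, in log2 units above the mean of the 3 control arrays (y axis), by group (x axis), with the mean and SD of each group as a bar (n = 3). Heat shock genes are highest in ventilation replicate 2 (1.67), and skeletal muscle genes in ventilation replicate 3 (1.98) and rhPBEF replicate 2 (2.82).

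The effect of rhPBEF in ventilated mice was read from the combined group against the ventilated group. The same chemokine genes led, with Cxcl3 at 47.8-fold, Cxcl2 at 23.0-fold, Ccl20 at 19.9-fold and Cxcl5 at 14.8-fold. Ccl20 rose from 7.15 ± 0.36 to 11.46 ± 0.38 (SD, n = 3 each, limma adjusted p = 0.00119). Slc26a4 rose 8.93-fold. The 2 falling genes were Krtap17-1, a keratin-associated protein gene, which fell by 2.35 ± 0.25 (SE), and Btc, which fell by 1.02 ± 0.13. In total 42 genes passed, 40 higher and 2 lower, 33 of them at least 2-fold, and 1290 had an unadjusted p under 0.05.

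Chemokines rose for 5 of 26 members, or 14 adjusted over the list alone (list adjusted p = 3.45e-19, adjusted p = 0.122 with an estimated correlation). Of 18 NF-kB targets and regulators 4 rose, or 14 adjusted over the list alone, and all 18 were positive (list adjusted p = 7.78e-21, adjusted p = 0.122 with an estimated correlation). Nfkbie, an inhibitor of NF-kB, rose 4.10-fold, Tnfaip2 3.94-fold and Tnfaip3 3.55-fold, while Cd83 stood at 4.70-fold (adjusted p = 0.0638). Toll-like receptor and acute phase genes rose for 2 of 17, or 11 adjusted over the list alone (list adjusted p = 3.77e-14, adjusted p = 0.183 with an estimated correlation). The largest differences of that list did not pass, with Saa3 at a log2 difference of 3.70 (adjusted p = 0.0527), Saa1 at 10.4-fold, Ptx3 at 6.69-fold and Orm1 at 6.49-fold. Csf3 alone of 15 inflammatory cytokines rose, 7.82-fold, and 6 did adjusted over the list alone (list adjusted p = 2.16e-07, adjusted p = 0.445 with an estimated correlation). Csf2 stood at 6.39-fold, Il6 at 5.43-fold (adjusted p = 0.210) and Il1rn at 2.64-fold.

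Sod2 rose 2.78-fold as the single member past of 19 oxidative stress genes, of which 4 rose adjusted over the list alone (list adjusted p = 5.74e-08, adjusted p = 0.122 with an estimated correlation). Slc7a11, encoding the cystine transporter, stood at 3.16-fold (adjusted p = 0.129), Mt1 at 1.57-fold and Gclm at 1.52-fold. All 14 heat shock genes were negative with none past in either adjustment (list adjusted p = 0.000106, adjusted p = 0.597 with an estimated correlation), and the list p was 0.351 without ventilation replicate 2. Hsph1 stood at -2.03, Hspa1a at -1.69, Hspe1 at -1.41 and Hspa1b at -1.30. The count of 42 genes was 406 without rhPBEF plus ventilation replicate 3, 17 without its replicate 1, 13 without its replicate 2, 16 without ventilation replicate 1, 23 without ventilation replicate 2 and 26 without control replicate 2. A fit on only the 6 arrays compared gave 3 genes, and counting all probe sets gave 65.

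The effect of ventilation after rhPBEF was read from the combined group against the rhPBEF group. Acaa1b, a peroxisomal thiolase gene of fatty acid oxidation, fell by 1.47 ± 0.16 (SE), from 9.19 ± 0.15 to 7.73 ± 0.20 (SD, n = 3 each, limma adjusted p = 0.0273). It was the only gene past, and 487 had an unadjusted p under 0.05. Immediate early genes were higher as a list (23 of 26 positive, 0 past in either adjustment, list adjusted p = 0.00128, adjusted p = 0.862 with an estimated correlation), with Fosl1 at 2.14-fold, Atf3 at 2.09-fold, Nr4a1 at 1.75-fold and Nr4a2 at 1.68-fold. All 18 NF-kB targets and regulators were positive with none past in either adjustment (list adjusted p = 0.0147, adjusted p = 0.862 with an estimated correlation). The prostaglandin synthase gene Ptgs2 stood at 2.51-fold, Selp at 1.72-fold, Nfkbiz at 1.45-fold and Vcam1 at 1.30-fold. Endothelial markers were lower as a list, 0 of 22 past and 3 falling adjusted over the list alone (list adjusted p = 0.0278, adjusted p = 0.862 with an estimated correlation), with Eng at -0.54 ± 0.09 (SE, adjusted p = 0.217), Sox18 at -0.99, Tmem100 at -0.59 and Egfl7 at -0.44.

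Skeletal muscle genes were lower as a list in that comparison (0 of 9 past in either adjustment, list adjusted p = 0.0186, adjusted p = 0.862 with an estimated correlation), with Tnni2 at -1.29, Tnnt3 at -1.14, Acta1 at -1.11 and Mylpf at -1.09, and all 4 were positive without rhPBEF replicate 2. Without the 2 arrays high in skeletal muscle genes the list was higher instead (median 0.145, adjusted p = 0.0465). The Acaa1b call was lost without any single array except ventilation replicates 1, 2 and 3 and rhPBEF plus ventilation replicate 3. Without rhPBEF plus ventilation replicate 1 the p of the immediate early, NF-kB and endothelial lists became 0.178, 0.844 and 0.184. Without replicate 2 of that group 1 list passed in this comparison, in place of 4.

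The interaction asked whether ventilation acted differently after rhPBEF. No gene passed with limma (smallest adjusted p = 0.998), and 288 had an unadjusted p under 0.05. The 5 genes with the smallest p were Krtap17-1 at -1.64 ± 0.36 (SE), Fgg at -1.0 ± 0.22, Traf1 at 0.89 ± 0.22, Cxcl2 at -2.91 ± 0.73 and Lrrfip1 at -0.55 ± 0.14. Neutrophil markers had a median interaction of -1.16, with 0 of 17 past and 2 lower adjusted over the list alone (list adjusted p = 8.38e-14, adjusted p = 0.563 with an estimated correlation), and S100a9, Mmp8, S100a8 and Clec4d stood at -3.09, -2.69, -2.67 and -2.49. Immediate early genes had a median of -0.33 (0 of 26 past in either adjustment, list adjusted p = 5.07e-09, adjusted p = 0.563 with an estimated correlation), with Fosb at -1.72, Egr2 at -1.54, Fos at -1.32 and Junb at -0.85. Inflammatory cytokines had a median of -0.50 (0 of 15 past in either adjustment, list adjusted p = 7.16e-06, adjusted p = 0.563 with an estimated correlation). Il1b, Il6, Tnfsf9 and Osm stood at -2.33, -2.27, -1.69 and -0.98. Chemokines had a median of -0.40 (0 of 26 past in either adjustment, list adjusted p = 0.000892, adjusted p = 0.563 with an estimated correlation), where Ccl3, Cxcl3 and Ccl12 stood at -1.61, -1.20 and -1.19. The chemokine list p was 0.887 without rhPBEF plus ventilation replicate 3. Without ventilation replicate 3 the interaction had 4 genes past.

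**Figure D3:**
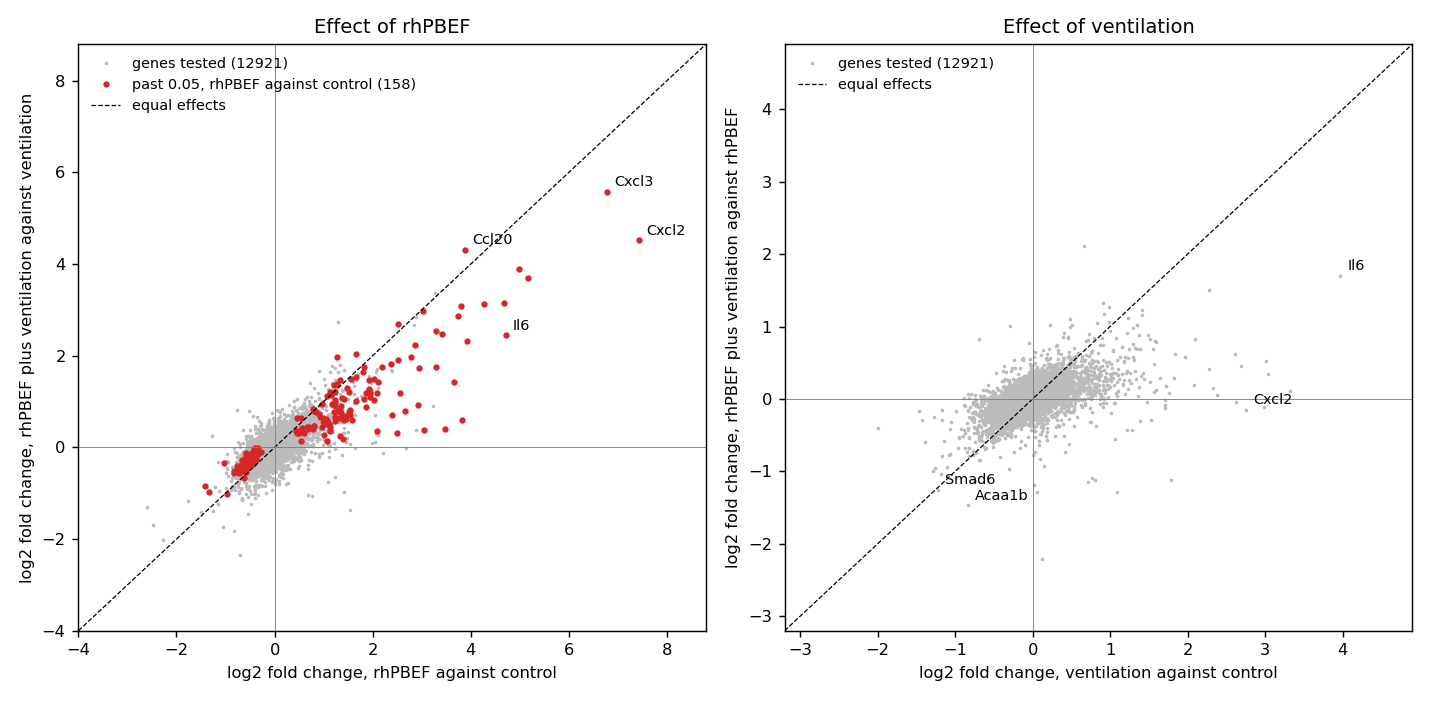
Log2 fold change of each of 12921 genes for rhPBEF without ventilation (x axis) against rhPBEF with ventilation (y axis), left, and for ventilation without rhPBEF against ventilation after rhPBEF, right. Red points, drawn in the left panel alone, are the 158 genes past 0.05 for rhPBEF against control, all with the same sign on both of its axes, and dashed lines mark equal effects.

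The effects of each treatment with and without the other were compared over genes, using fold changes that share no arrays. The rhPBEF effects correlated at r = 0.752 across 12921 genes, which are not independent replicates, with a slope of 0.597. All 158 genes called for rhPBEF against control kept their sign in ventilated mice, and 36 of them passed there too. The ventilation effects correlated at r = 0.555 with a slope of 0.336, and r was 0.267 without rhPBEF plus ventilation replicate 1. Noise in the fold changes on the x axis lowers both slopes. The slopes therefore do not show that either effect was weaker beside the other treatment. Ventilation and rhPBEF were each compared with the same control arrays. Their fold changes against those controls correlated at r = 0.607, where simulated groups with no effect gave 0.501, and 71.1% of genes had the same sign, against 66.6% simulated. The covariance was 0.0582 against 0.0159 simulated, a difference of 0.0422. No gene was called in both, the simulation gave 0, and independent lists would share 0 higher and 0.00286 lower genes. With 1 call for ventilation an overlap could hardly arise, so that count decides little, and it ranged from 0 to 24 with 1 array left out. Of the 158 genes called for rhPBEF, 136 had the same sign after ventilation, read against the same controls. The 3 controls are too few to be split into parts of 2, so some of the excess in correlation, covariance and sign may come from sharing them.

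Nampt, the mouse gene for PBEF, was reported for each comparison. Its log2 level was 10.50 ± 0.12 (SD, n = 3) in control, 10.57 ± 0.11 after ventilation, 10.60 ± 0.05 after rhPBEF and 10.87 ± 0.24 after both. It did not pass in any comparison. The log2 difference from control was 0.07 ± 0.12 (SE, adjusted p = 0.783) for ventilation, 0.11 ± 0.12 (adjusted p = 0.677) for rhPBEF and 0.37 ± 0.12 (adjusted p = 0.0732) for both. The combined group stood 0.30 above the ventilated and 0.27 above the rhPBEF group, and the interaction was 0.19 ± 0.17. Of its 3 probe sets 2 had the opposite sign for ventilation. The probe sets measure mouse RNA, so they do not check the delivery of a human protein.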

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

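The tests of skeletal muscle, heat shock, endotoxin and water below were chosen only after the results were seen, while the counts of other splits of the arrays were planned.

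The ventilation effect with rhPBEF differed from that without it for 14 gene lists by the interaction term, with camera's preset correlation. With an estimated correlation 0 lists passed (lowest adjusted p = 0.563), and limma called 0 genes (288 at an unadjusted p under 0.05). The median interaction was negative for inflammatory cytokines (-0.496), chemokines (-0.398), immediate early genes (-0.331), NF-kB targets and regulators (-0.132) and Toll-like receptor and acute phase genes (-0.374). It was also negative for stretch and matrix injury genes (-0.174), neutrophil markers (-1.16), B cell markers (-0.166), skeletal muscle markers (-1.14) and mesothelial markers (-0.312). It was positive for ciliated cell (0.292), endothelial cell (0.209), smooth muscle (0.378) and adipocyte markers (0.757). Of 100 splits of the arrays, 48 gave at least the 14 real lists (highest other 23). The splits drew group labels over all 12 arrays, so they mix the rhPBEF and ventilation effects into the interaction. They ask about no effect of any kind, cannot decide on the interaction alone, and leave chance not excluded for the lists. Every split gives at least the real 0 genes (100 of 100, highest other 4), so that count decides nothing. Without the 2 arrays high in skeletal muscle genes the skeletal muscle list turned positive (0.443, adjusted p = 0.00999). There the NF-kB (adjusted p = 0.0992), stretch (adjusted p = 0.0703), B cell (adjusted p = 0.208) and mesothelial (adjusted p = 0.0598) lists no longer passed, and the 9 others passed with the same direction. Without rhPBEF plus ventilation replicate 3, 8 lists passed in place of 14. Among those lost, the adjusted p of the chemokine list was 0.887, of the Toll-like receptor list 0.824 and of the inflammatory cytokine list 0.0606.

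Probe sets that do not carry a single gene symbol entered no comparison of genes. Of 4111 such probe sets past the filter, 25 passed 0.05 for rhPBEF against control (24 higher) and 183 for rhPBEF plus ventilation against control (100 higher). They were not interpreted.

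Skeletal muscle genes were high in ventilation replicate 3 and rhPBEF replicate 2 alone, with Acta1 at 11.48 and 12.28 against 6.41 to 7.64 in the other 10 arrays. A response to ventilation or rhPBEF is argued against by the other 4 arrays of those groups, whose highest list mean was -0.117. Heart muscle as the source is argued against by control replicate 1. Its cardiac list mean was the highest (0.58), but its skeletal muscle list mean was 0.22, against 1.98 and 2.82 in the 2 arrays. The cardiac list means of the 2 arrays, 0.102 and 0.186, lay above control replicates 2 and 3 (-0.43 and -0.16), so some heart muscle in them stays open. Skeletal muscle carried into those 2 samples may explain the pattern, since 8 of 9 list members were higher in both arrays than in every other array, although the pattern was noticed with this same list. Without the 2 arrays the count of genes was 34 for ventilation against control and 69 for rhPBEF against control, where the fits on all arrays gave 1 and 158.

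Heat shock genes were high in ventilation replicate 2, at a list mean of 1.67. A rise common to ventilated lungs is argued against by the other 2 ventilated arrays (higher list mean -0.121). A stronger response to ventilation in replicate 2 stays open. Its immediate early (1.60 against 0.40 and 0.39) and NF-kB (0.86 against 0.40 and 0.31) list means were the highest of the group. Its neutrophil mean (2.14 against 2.28 and 0.49) was not. Degraded RNA is argued against by the 3' minus 5' difference of the Actb control probe sets, 0.368 against 0.353 to 0.543 in the other arrays (Gapdh 0.0173 against -0.114 to 0.0947). A warmer animal or tissue may also explain the pattern, since Cirbp, a cold-induced gene, was 1.76 log2 units lower in that array than the lowest other array (difference -1.76). No temperature is given in the labels, so this rests on 1 array and 1 gene.

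The rises of chemokine, NF-kB and Toll-like receptor genes after rhPBEF cannot be told apart from effects of endotoxin carried with a recombinant protein, because 0 groups received inactivated protein or endotoxin. They cannot be told apart from an effect of instilled water either, because control mice received saline and 0 groups received water alone. Both stay open beside an effect of the protein itself, and the design confounds all 3.

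With 3 arrays against 3 there are 10 splits, so the share of splits as large cannot be under 0.05. Every other split puts arrays of both groups on each side. Part of a real difference then stays between the sides and the rest enters the spread. Where a real difference is large, few genes can pass in such splits, so their gene counts do not measure noise alone. Lists passing there may also hold part of a real difference. For rhPBEF against control 1 of 10 splits gave the real 158 genes (highest other 0) and 4 gave at least 16 lists (highest other 21). For ventilation against control 1 of 10 gave 1 gene (highest other 0) and 1 gave 18 lists (highest other 16). For both against control 1 gave 1136 genes (highest other 0) and 5 gave at least 14 lists (highest other 18). For both against ventilation 1 gave 42 genes (highest other 0) and 7 gave at least 12 lists (highest other 18). For both against rhPBEF 2 gave at least 1 gene (highest other 14, with replicates 1 and 2 of the combined group on the side of rhPBEF replicate 1) and 10 gave at least 4 lists (highest other 20). That split of 14 genes points to a structure of the samples. It set rhPBEF plus ventilation replicate 3 (chemokine list mean 1.29) apart from replicates 1 and 2 (2.54 and 2.28), but the 2 other splits that did so gave 0 genes. That replicate also had the highest 3' minus 5' differences of the 12 arrays, 0.543 for Actb and 0.0947 for Gapdh, and rhPBEF replicate 3, on its side of the split, the next highest for Actb (0.471). Leaving out rhPBEF plus ventilation replicate 3 moved the count of both against control from 1136 to 2498 and of both against ventilation from 42 to 406. A difference in RNA quality stays open there and was not tested.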

How the results depend on the processing

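The fit without the 2 arrays high in skeletal muscle genes (ventilation replicate 3 and rhPBEF replicate 2) was chosen only after seeing the data; the other alternatives were planned. Values were already log2, so no pseudocount was varied. Of the single-gene values 3881 kept direction and side of the threshold, 313 lost and 88 gained a call, and 25 reversed. Counts and correlations were within the set margin 239 times and moved 83 times. The margin was a fixed ratio for counts, and for correlations the standard error from leaving out each array. It was wide: 20 lists in place of 14 for the interaction lay within it. Calls held under all alternatives for 14 of 33 named genes for rhPBEF against control, 18 of 39 for both against control, 2 of 12 for both against ventilation, and 0 of 1 for ventilation against control and for both against rhPBEF, always with the same sign.

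With an estimated correlation 0 lists passed in all 6 comparisons, where 18, 16, 14, 12, 4 and 14 had. The correlations estimated from the residuals lay above the preset 0.01 for every list, from 0.04 (NAD metabolism) to 0.94 (cardiac muscle). They were 0.58 for immediate early genes and 0.69 for neutrophil markers. Mixed splits of the arrays also passed lists at the preset value, up to 21 for rhPBEF against control, although such splits keep part of a real difference. Given the estimated correlations, the list p-values with the preset correlation may be too small. For ventilation against control the 1 gene became 4 with an intensity trend and robust settings, 4 with the mean of all probe sets, 3 when all probe sets were counted, 0 with the replicate block, 0 with only the 2 groups compared and 34 without the 2 muscle-high arrays. For rhPBEF against control 158 became 636 with only the 2 groups and 69 without the 2 arrays, and for both against ventilation 42 became 3 with only the 2 groups and 65 over all probe sets. For both against rhPBEF 1 gene became 2 with the mean of probe sets, and 0 with the replicate block, only the 2 groups, all probe sets or without the 2 arrays; its 4 lists became 2 with the filter at the 60th percentile, 7 with the replicate block, 7 with only the 2 groups and 10 without the 2 arrays. Without the 2 arrays the interaction had 2 genes, and ventilation and rhPBEF shared 15 calls in place of 0. The cause was not tested. The replicate numbers were not taken to pair the arrays: 18 same-number pairs correlated at -0.21 to 0.53 with a median of 0.065, 7 of them over 0.1, and 1 array matched its own number best in every group. Different-number pairs ran from -0.530 to 0.328, below the highest same-number values (0.526, 0.356 and 0.337). A factor shared by replicate number is therefore not excluded.

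Leaving out 1 array gave 0 to 43 genes for ventilation against control, 44 to 358 for rhPBEF against control, 152 to 2498 for both against control, 13 to 406 for both against ventilation, 0 to 3 for both against rhPBEF and 0 to 4 for the interaction. Lists ranged from 17 to 20, 15 to 17, 13 to 17, 11 to 15, 1 to 17 and 8 to 20 in the same order. The correlation of ventilation effects ranged from 0.267 to 0.605, that of rhPBEF effects from 0.619 to 0.791, and shared calls from 0 to 24.

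The difference of Nampt for ventilation was -0.092 with the mean of its probe sets. Leaving out 1 array, ventilation against control ranged from -0.035 to 1.56 for Bag3, -0.30 to 1.31 for Chordc1 and -0.36 to 1.21 for Stip1 (lowest without ventilation replicate 2), -1.43 to 0.50 for Dnajb1 (0.07 without control replicate 3), and -0.052 to 1.22 for Mylpf and -0.23 to 1.31 for Tnnt3 (lowest without ventilation replicate 3). For rhPBEF against control Acta1 ranged from -0.37 to 2.56, Tnnt3 from -0.13 to 1.99 and Mylpf from -0.18 to 1.78, and for both against rhPBEF Tnni2 from -2.0 to 0.10, Tnnt3 from -1.91 to 0.22, Acta1 from -2.14 to 0.79 and Mylpf from -1.77 to 0.19, with the opposite sign without rhPBEF replicate 2. Without both muscle-high arrays Dnajb1, Mylpf, Tnnt3 and Acta1 took the same opposite values (0.50, -0.052, -0.23, -0.37, -0.13 and -0.18, and 0.10 for Tnni2, 0.22, 0.79 and 0.19). The muscle reversals follow from those arrays' levels; for the others the cause was not tested.

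Background limits the folds of genes with low control levels, since no detection calls come with the values.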

Other observations

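The average of the 2 ventilation contrasts, the repeat of top genes and the relation of heat shock genes to Cirbp were tests chosen only after the results were seen; the direction of pathway members not yet looked at and the splits of the averaged contrast were predicted before their values were seen. The first draw of those splits held repeats, so the splits were drawn again without repeats after its values were seen.

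The average of the ventilation effects with and without rhPBEF (6 arrays against 6) called 71 genes with limma, 32 higher and 39 lower. Il6 rose 7.14-fold (log2 2.84 ± 0.47, SE, adjusted p = 0.0386), Trim15 2.44-fold, Gpr65 2.27-fold and Noct, a gene with circadian expression, 2.18-fold. Smad6 fell by 1.24 ± 0.17, Acaa1b fell by 1.15 ± 0.12, and the flow-responsive endothelial gene Klf2 fell by 1.11 ± 0.16. Ephb4 fell by 0.68 ± 0.07 (adjusted p = 0.00456). Of 22 endothelial markers 3 fell and 0 rose (camera adjusted p = 0.000366, adjusted p = 0.523 with an estimated correlation). Of 100 different splits drawn from the 200 that kept the rhPBEF groups, 3 gave at least 71 genes, the real one included (highest other 693), and 21 gave at least the 18 lists (highest other 22). With an estimated correlation 0 of the 35 lists passed (lowest adjusted p = 0.523). The share for genes among those drawn is under 0.05, but 2 splits gave 447 and 693 genes, which points to a structure of the samples. Both kept all control against all ventilation arrays, so they hold the real contrast of that arm, and both set rhPBEF plus ventilation replicate 3 on the control side and replicates 1 and 2 on the ventilation side. Another split with that arm kept and the 3 replicates on the reverse sides gave 0 genes. Splits that set replicate 3 apart but mixed control and ventilation arrays gave 0 to 3 genes. What set the 2 splits off was not tested further. The count was 6 without control replicate 1 or rhPBEF replicate 1, 8 without control replicate 2 or rhPBEF plus ventilation replicate 1, 9 without rhPBEF plus ventilation replicate 2, 10 without rhPBEF replicate 3, 39 without control replicate 3 and 555 without rhPBEF plus ventilation replicate 3.

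Genes that ranked first in ventilation against control were looked up in a contrast of the other arrays, although the p-values that ranked them use the spread of all 12 arrays. Of the 50 with the smallest p among falling genes 98% were also negative in rhPBEF plus ventilation against rhPBEF (median -0.53 and then -0.23), where 95% of random sets matched on expression gave 34 to 62%. Of 50 rising genes 90% were positive there (median 1.09 and then 0.28), with 38 to 64.05% in random sets. The random sets were not required to share the first direction, so they set a low bar. Over all 12921 genes 68.3% had the same sign in both contrasts. The shares of 98% and 90% may reflect a ventilation effect common to both arms, although genes are not independent. The first medians are raised by the choice of genes on them, so the 2 medians do not compare the size of the effects.

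Several falling genes, Eng, Acvrl1, Smad6 and Id1, belong to endothelial BMP and ALK1 signalling, with averaged log2 changes of -0.60, -0.57, -1.24 and -0.65. A fall across that pathway was tested on 9 members not looked at before. Their median was -0.0547 (random lists -0.126 to 0.096), 5 of 9 were negative and none passed with limma, with Hey1 at -0.53, Smad7 at -0.51 and Smad1 at 0.42. This argues against a fall of the whole pathway by the size seen in the first members.

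Heat shock genes varied within groups, and their list mean was compared with Cirbp over the 12 arrays, the only relation tested. With group means removed r was -0.912 and rho -0.734 (permutation p = 0.00066 and 0.009), and with them kept r was -0.874 and rho -0.678 (permutation p = 0.00116 and 0.0183). All these permutations shuffled Cirbp over the arrays without regard to group. Values with group means removed depend on each other within a group, so their permutation p-values may be too small. Those with group means kept ignore the groups. Without ventilation replicate 2 and rhPBEF plus ventilation replicate 3, the 2 farthest arrays, r was -0.816 and rho -0.539 with group means removed (permutation p = 0.0179 and 0.114), and r was -0.602 and rho -0.491 with them kept (permutation p = 0.0682 and 0.156). The removed group means were taken over all 12 arrays, so the 2 left-out arrays still shift the values with group means removed. Those values therefore do not show whether the relation holds without the 2 arrays. Differences in body or tissue temperature between animals may explain the relation, which rests in part on those 2 arrays. A further cold-induced gene, Rbm3, was not analysed here because its probe sets carry more than 1 symbol.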
